A study of Mus musculus with 59 samples.

How the data were processed

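Transcripts were measured by RNA sequencing in primary mouse microglia, the resident macrophages of the brain, grown from newborn pups. Per the labels, the cultures came from 3 genotypes of a conditional Tbk1 allele: WT carried the floxed allele without Cre recombinase, HET carried 1 floxed copy with a Cre recombinase driven by Cx3cr1, and KO carried 2 floxed copies with the same Cre. Cells were plated for 16 h and then left untreated (UT) or given lipopolysaccharide (LPS, a bacterial cell wall component) at 100 ng/mL, interleukin-4 (IL4) at 20 ng/mL, or poly(I:C) (pIC, a synthetic double-stranded RNA) for 24 h. The dose of pIC is not given in the sources used here. Libraries were made from 300 ng of RNA with an mRNA kit, per the labels' protocols. There were 59 libraries in 12 groups of 5, except untreated WT with 4, whose replicate 5 was not analysed here. The labels speak of independent cultures for the replicates, 5 per genotype.

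The authors deposited the values per gene as TPM, a length-scaled share of the transcripts, in separate tables for the 44 untreated, LPS and IL4 libraries and for the 15 pIC libraries, each with 32070 genes. TPM divides the reads of each gene by gene length and scales every library to the same total, so depth per library is unknown and a rise in a few abundant genes lowers the values of all others. The summed TPM ran from 999806 to 999936 per library. The submitters' processing notes name FastQC, Trimmomatic, DRAGEN and Picard and the mm10 build, without versions or order. The strand setting of the counting is not given in the sources used here, so genes that overlap on opposite strands, near-identical copies and pseudogenes cannot be told apart with certainty. No columns were identical, and the highest Pearson correlation between any libraries, across genes, was 0.994 (HET pIC 5 and WT pIC 5).

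TPM values were transformed as log2(TPM + 1), so a log2 difference understates the change of genes with low values. Genes with at least 1 TPM in at least 4 libraries of a table were tested: 15908 among the untreated, LPS and IL4 libraries and 13919 among the pIC libraries. The test was limma's moderated test (limma 3.58.1 with lmFit and eBayes with a trend, R 4.3.3, data.table, version 1.17.8) with a mean per group and all groups of a table sharing an estimate of the spread. P-values were adjusted over genes by the Benjamini-Hochberg method and called at 0.05, and every adjusted p given for a gene comes from this test. No test was made between the tables, and levels set side by side across them are descriptive. The 22 comparisons were KO against WT, HET against WT and KO against HET within each treatment, LPS or IL4 against UT within each genotype, and the differences of those responses between genotypes. Because WT lacked Cre, differences from WT also hold Cre and the chromosome that carries it, while KO against HET holds Cre constant.

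Gene lists for 34 functions and cell types were fixed before the data were examined, as were the lists' tests, the rule for named genes and the alternatives, except where said otherwise. Each list was tested with limma's camera function with a preset correlation of 0.01 between genes and again with an estimated correlation, with adjustment over the lists of a comparison, 32 lists in each. Over all comparisons, 299 of 704 list tests passed with the preset correlation, and 62 of those passed with the estimated one, so the estimated value is given wherever it removes a call. Counts of members are given over all genes tested and, where they differ, adjusted over the list alone. Genes named were Tbk1 and Cx3cr1 in every group, then the 6 highest and 6 lowest called differences (3 and 3 in the smaller comparisons) with a mean of at least 5 TPM in the higher group and no overlap between libraries, without predicted or pseudogene models, and up to 4 called members per list. Other names were chosen after their values were seen and are marked so. Some genes that the rule names are not reported here.

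The procedure was tested on simulated data made from the real libraries, with 100 genes changed by 1 and 100 by 2 on the log2 scale. For KO against WT it recovered 89% and 98% untreated, 86% and 100% under LPS, and 87% and 100% under pIC. For IL4 against UT in WT it recovered 88% and 100%, and for the difference between the LPS responses of KO and WT 73% and 93%. Between 3.49% and 5.1% of the calls were false in these 5 simulated comparisons, 5 shifted lists were recovered and 0 unshifted lists were called by camera. The changed genes were drawn from those with means above about 5 TPM. The simulated noise was independent between genes and libraries, with 1 spread per gene in all groups. These rates therefore do not cover correlated genes, shared cultures or unequal spreads, and do not show error control of the list tests in the real data.

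Alternatives were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, quantile normalization, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. A covariate for the Xist level of each library and a fit without replicate 5 of every group were added after the data were seen. Genotypes could share a replicate number by design or by naming, so the numbers were taken to pair the libraries only where every pair of same-numbered libraries deviated together from its group means, with a correlation above 0.1 across genes. That held for HET against WT untreated (lowest pair 0.121), LPS against UT in WT (0.117) and KO (0.13), and IL4 against UT in WT (0.191) and KO (0.173). Within a genotype the libraries of a number also held the same sex-chromosome transcripts in every treatment, so they were taken as one culture. HET libraries were therefore read as paired across treatments too, although not every HET pair passed that correlation. Positions are from GENCODE M21 on GRCm38 (mm10).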

Results

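The libraries held between 12428 and 14581 genes with at least 1 TPM, and the 50 most abundant genes took from 23.4% to 38.3% of the summed TPM. Depth per library is unknown, because TPM keeps none. Values are given as mean TPM ± SD over 5 libraries, or 4 for untreated WT, and log2 differences of log2(TPM + 1) as estimate ± SE from limma.

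Tbk1 encodes a kinase that links sensors of bacterial products and nucleic acids to type I interferon and also acts in autophagy and cell death control. The gene (Entrez 56480) lies on the minus strand of chromosome 10 from 121546455 to 121586787. Its transcript followed the genotype in every treatment. Untreated cultures had 47.5 ± 4.17 TPM in WT (n = 4), 34.9 ± 1.67 in HET (n = 5) and 19.9 ± 4.74 in KO (n = 5). With LPS the values were 90.9 ± 8.37, 60.5 ± 4.08 and 18.0 ± 5.14, with IL4 44.0 ± 1.69, 31.0 ± 2.53 and 15.6 ± 4.89, and with pIC 82.5 ± 6.17, 53.9 ± 6.04 and 23.8 ± 4.64. KO was below WT by -1.24 ± 0.15 untreated, -2.31 ± 0.14 with LPS, -1.49 ± 0.14 with IL4 and -1.77 ± 0.11 with pIC on the log2 scale, and the adjusted p was at most 6.53e-06. HET values lay between, by -0.43 ± 0.15, -0.58 ± 0.14, -0.49 ± 0.14 and -0.61 ± 0.11 against WT, and none passed adjustment over all genes (adjusted p = 0.998, 0.274, 1 and 0.215 in the same order). A value per gene sums reads from all exons, so it does not show whether the deleted exon was absent.

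**Figure D1:**
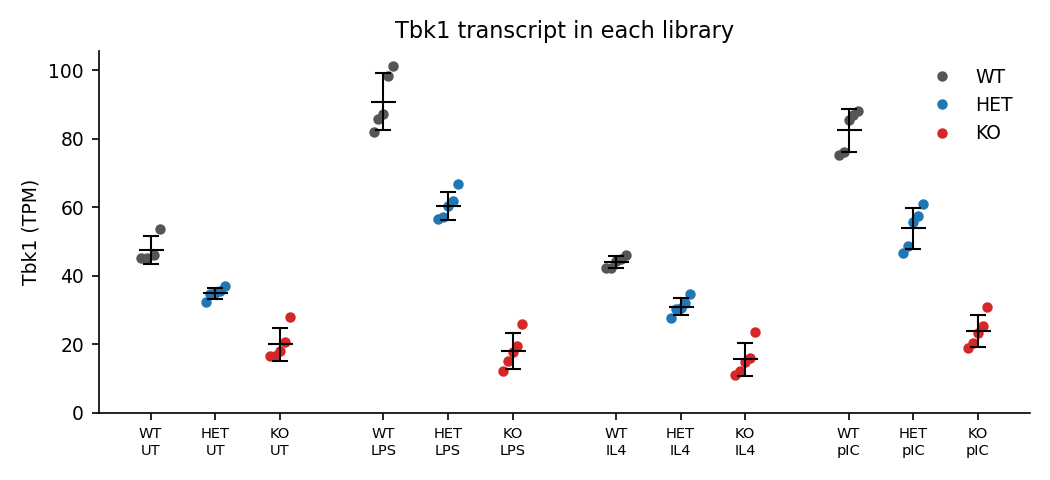
Tbk1 transcript in TPM (vertical axis, linear from 0) in each of the 59 libraries, grouped by genotype and treatment along the horizontal axis. Points are libraries and bars are mean ± SD. KO means lie between 15.6 and 23.8 TPM in all 4 treatments, and WT means rise from 47.5 untreated to 90.9 with LPS.

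Cx3cr1, the fractalkine receptor of microglia and the gene whose driver was used for Cre, was at 761 ± 72.5 TPM in untreated WT, 866 ± 71.1 in HET and 793 ± 66.5 in KO. It fell with LPS to 35.2 ± 15.3 in WT, 38.3 ± 9.90 in HET and 78.3 ± 35.2 in KO, and with IL4 to 312 ± 57.9, 322 ± 63.2 and 292 ± 36.3. In the pIC table it was at 69.2 ± 18.9, 110 ± 54.5 and 211 ± 200, and the KO mean of Cx3cr1 was 126 ± 73.8 without KO pIC 4. KO exceeded WT under LPS by 1.11 ± 0.21 (adjusted p = 4.37e-05). The other differences of Cx3cr1 from WT did not pass, with adjusted p from 0.15 for KO under pIC to 1.

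The first question was what LPS does to WT microglia. Genes of inflammation and innate defence rose by the largest amounts. Il1a, an alarm cytokine, went from 1.96 ± 0.706 to 8187 ± 3370 TPM (log2 difference 11.36 ± 0.38), and Ccl5, a chemokine for T cells, from 5.27 ± 2.29 to 13020 ± 1810. Mmp13, a collagenase, went from 3.24 ± 0.520 to 5461 ± 1280, Acod1, which makes itaconate, from 1.68 ± 1.83 to 3001 ± 705, and Cxcl2, a neutrophil attractant, from 2.60 ± 2.26 to 3968 ± 1710. Il6 was listed at 0 in all untreated WT libraries and at 1977 ± 832 with LPS. Genes typical of resting microglia fell: the receptor Gpr34 by -6.83 ± 0.18, Trem2 by -6.29 ± 0.27, the prostaglandin-degrading enzyme Hpgd by -6.66 ± 0.23, the exchange factor Rasgrp3 by -5.99 ± 0.24 and the transporter Slco2b1 by -5.81 ± 0.24. Trem2, a lipid-sensing receptor, went from 910 ± 65.3 to 12.6 ± 7.70 TPM.

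Whole lists moved with these genes. All 32 tested NF-kB target and inflammatory cytokine genes rose with LPS in WT (median 4.28, adjusted p = 4.89e-42 by limma's camera), as did all 40 interferon-stimulated genes (median 4.72), led by Rsad2 (7.79 ± 0.54), Oasl1 (7.68 ± 0.42) and Isg15 (7.35 ± 0.37), and all 20 genes of MHC class I presentation (median 2.54). Of the 21 chemokines tested 15 rose and 3 fell. Of the 19 glycolysis genes 18 rose, with the lactate exporter Slc16a3 at 3.77 ± 0.18 and the glucose transporter Slc2a1 at 3.36 ± 0.15, and of the 21 genes of the unfolded protein and integrated stress response 16 rose, with Trib3 at 3.11 ± 0.29 and Ddit3 at 2.51 ± 0.16. Of 27 genes around RIPK1 and cell death 18 rose and 6 fell, with the necroptosis genes Zbp1 at 6.25 ± 0.25 and Mlkl at 5.59 ± 0.21 among those that rose. All 20 homeostatic microglia genes tested fell (median -2.65). Each of these list calls held with an estimated correlation (adjusted p at most 0.00581).

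Cholesterol synthesis fell as a group, 22 of 22 genes with a median of -2.08, including Idi1 (-2.71 ± 0.28), Dhcr7 (-2.68 ± 0.20) and Hmgcs1 (-2.66 ± 0.29). Of 39 cell cycle genes 37 fell, with the histone Cenpa at -2.91 ± 0.25 and the nucleotide reductase Rrm2 at -2.69 ± 0.29. With an estimated correlation the list tests of cholesterol synthesis and cell cycle did not pass (adjusted p = 0.448 and 0.498). Under median-of-ratios scaling and quantile normalization the medians stayed below 0, and 33 of the cell cycle genes were lower under either. The cultures also held transcripts of other brain cells. On the TPM scale most of those of oligodendrocytes, neurons and astrocytes were lower with LPS, as were 9854 of all 15908 genes tested. The oligodendrocyte gene Olig1 went from 465 ± 121 to 89.1 ± 58.8 TPM, Mbp from 356 ± 186 to 77.9 ± 53.7 and the neuronal Map2 from 151 ± 34.5 to 40.3 ± 13.8. Of these lists, 13 of 14 oligodendrocyte lineage markers, 8 of 12 neuron markers and 8 of 11 astrocyte markers (9 adjusted over the list alone) fell, while 1 astrocyte marker rose (list tests not passed, adjusted p = 0.298, 0.642 and 0.411). In the same order, 10, 8 and 6 markers were lower with median-of-ratios scaling, and 10, 5 and 6 with quantile normalization. Under either, 1 neuron marker and 1 astrocyte marker were higher. Endothelial, pericyte and fibroblast markers went both ways, 5 of 12 higher and 4 lower with median-of-ratios scaling, and 5 and 2 with quantile normalization.

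In all, limma called 2210 genes higher and 9854 lower with LPS in WT, 2275 and 9497 in HET, and 2085 and 8993 in KO. The large excess of lower genes rests on the scaling. The median gene shifted by -0.588 in WT, -0.514 in HET and -0.444 in KO on the TPM scale, and the 50 most abundant genes took 33.5% of TPM with LPS against 27.6% without it in WT. With median-of-ratios scaling the calls were 5024 higher and 5139 lower in WT, 5134 and 5186 in HET, and 4669 and 4629 in KO, and with quantile normalization 4034 and 5750, 4055 and 5612, and 3777 and 5126. Oxidative phosphorylation genes, 28 of 33 lower with LPS on the TPM scale (median -0.503), had 17 higher and 3 lower with median-of-ratios scaling (median 0.173), so no direction is given for them. The share of TPM from the mitochondrial genome was 4.34 ± 0.706% in untreated WT and 2.50 ± 0.234% with LPS. The same holds for autophagy genes, with a median of -0.379 against 0.287.

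In HET the leading LPS responses were those of WT: Il1a at 11.68 ± 0.35, Cxcl2 at 11.00 ± 0.39, Gpr34 at -6.79 ± 0.17, Hpgd at -6.74 ± 0.22 and Trem2 at -6.24 ± 0.25, with Il6 again listed at 0 before LPS and at 2133 ± 290 TPM after it. In KO the top of the list held other names. Saa3, an acute phase protein, reached 66920 ± 25000 TPM from 37.5 ± 17.5 (10.81 ± 0.44), the scavenger receptor Marco 3165 ± 554 from 1.20 ± 0.974 (10.59 ± 0.33) and the chemokine Cxcl3 2373 ± 1550 from 0.430 ± 0.323 (10.45 ± 0.42). That order is within KO and does not compare genotypes, as Marco also rose in WT, by 7.6 on the log2 scale. Gpr34 (-6.62 ± 0.17), Hpgd (-6.00 ± 0.22) and the chemokine receptor Cxcr4 (-5.69 ± 0.22) fell most among the genes the rule names in KO. Tbk1 itself rose with LPS in WT (0.92 ± 0.15, adjusted p = 1.04e-06) and HET (0.78 ± 0.14, adjusted p = 7.12e-06) and was not called in KO (-0.15 ± 0.14, adjusted p = 0.338), where median-of-ratios scaling gave 0.35 (adjusted p = 0.0351) and quantile normalization 0.27.

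The central question was whether microglia without Tbk1 respond to LPS in another way. Under LPS the interferon-driven part of the response was far lower in KO than in WT. Of 40 interferon-stimulated genes 39 were lower and none higher (median -1.58, adjusted p = 6.24e-36 by limma's camera, and 0.0346 with an estimated correlation). Rsad2, an antiviral enzyme, was at 36.0 ± 45.6 TPM in KO against 968 ± 682 in WT (-5.19 ± 0.51), Oasl1 at 12.8 ± 16.8 against 264 ± 87.3 (-5.05 ± 0.40), Cmpk2 at 32.1 ± 35.7 against 539 ± 392 (-4.35 ± 0.47) and Ifit2 at 45.9 ± 63.6 against 444 ± 160 (-4.19 ± 0.48). KO LPS 1 stood highest in these, and without it the KO means were 16.2 for Rsad2, 5.80 for Oasl1, 16.9 for Cmpk2 and 18.4 for Ifit2. Cxcl10 and Ccl5, chemokines that interferon regulatory factors switch on, were lower by -5.41 ± 0.53 and -3.36 ± 0.43, and their list, of which only these 2 members could be tested here, passed with an estimated correlation (adjusted p = 0.0346).

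Antigen presentation by MHC class I followed, with 19 of 20 genes lower in KO (median -1.03, adjusted p = 0.0346 with an estimated correlation). H2-Q6 was at 8.76 ± 6.87 TPM against 373 ± 48.4 in WT (-5.52 ± 0.26) and H2-Q7 at 14.0 ± 8.16 against 365 ± 70.9 (-4.75 ± 0.25). These near-identical genes can share reads, so their values are not independent. H2-Q4 (-2.66 ± 0.16) and H2-T22 (-2.07 ± 0.14) were lower too. Of 16 immediate early genes 11 were lower and 2 higher in KO (adjusted p = 0.0346 with an estimated correlation), with the phosphatase Dusp1 at -2.24 ± 0.24, the RNA-binding Zfp36 at -1.81 ± 0.19, Klf6 at -1.62 ± 0.13 and Egr2 higher at 2.45 ± 0.34.

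NF-kB targets and cytokines were split. Of 32 tested, 18 were lower and 6 higher in KO (19 and 6 adjusted over the list alone, median -0.738), and the list test passed with the preset correlation (adjusted p = 2.96e-06) and not with an estimated one (adjusted p = 0.0805). The lower ones included Nos2, the inducible nitric oxide synthase, at 18.2 ± 13.0 against 892 ± 490 TPM (-5.60 ± 0.40), Ptgs2, the inducible cyclooxygenase (-3.18 ± 0.36), Il10 (-3.07 ± 0.26) and Il12b (-2.92 ± 0.34). Chemokines went both ways, 8 lower and 7 higher of 21: the monocyte attractants Ccl7 (-5.64 ± 0.46), Ccl2 (-4.70 ± 0.46) and Ccl12 (-4.49 ± 0.55) and the interferon-inducible Cxcl9 (-4.19 ± 0.19) were lower. Other genes that were far lower in KO were Ifit1bl1 (-6.45 ± 0.43), Slfn4 (-5.84 ± 0.32) and Ms4a4c (-5.62 ± 0.54). KO LPS 1 carried much of several KO means here. Without it that of Ccl7 went from 20.2 to 8.82 TPM and that of Ccl12 from 51.7 to 18.2. Ms4a4c went from 26.0 to 8.13 and Ifit1bl1 from 5.75 to 2.29.

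Another set of genes was higher in KO than in WT under LPS. Hp, which encodes the haemoglobin scavenger haptoglobin, was at 145 ± 50.0 TPM against 6.63 ± 3.30 in WT (4.30 ± 0.33), Itgax, the integrin CD11c, at 137 ± 103 against 5.25 ± 2.44 (4.14 ± 0.42), and Fn1, fibronectin, at 290 ± 96.7 against 24.2 ± 11.6 (3.61 ± 0.32). The phosphatase Acp5 was at 197 ± 88.4 against 15.9 ± 7.18 (3.55 ± 0.29), Susd2 at 48.0 ± 27.2 against 2.06 ± 0.765 (3.85 ± 0.23) and the guanine deaminase Gda at 27.8 ± 9.40 against 1.42 ± 0.533 (3.53 ± 0.28). Homeostatic microglia genes were higher in 10 of 20 (12 adjusted over the list alone) and lower in none, with Trem2 (2.70 ± 0.25), Tmem119 (2.30 ± 0.19), P2ry13 (1.41 ± 0.19) and Olfml3 (1.31 ± 0.21), although the list test missed the threshold with an estimated correlation (adjusted p = 0.0623). Of 22 cholesterol synthesis genes 21 were higher (Idi1 1.66 ± 0.27, Fdps 1.61 ± 0.29), of 17 NRF2 oxidative stress genes 12 were higher (Nqo1 2.80 ± 0.33, Gclm 1.65 ± 0.28) and of 33 oxidative phosphorylation genes 20 were higher (22 and 1 lower adjusted over the list alone, Ndufb3 0.62 ± 0.10, Cox6c 0.50 ± 0.08), with no member of any of the 3 lists lower over all genes. Transcripts of the mitochondrial genome took 3.92 ± 1.29% of TPM in KO with LPS (2.31% to 5.89%), 3.05 ± 0.992% in HET and 2.50 ± 0.234% in WT (2.26% to 2.88%). Glycolysis went the other way, 11 of 19 lower (Hk1 -1.33 ± 0.19, Hk3 -1.31 ± 0.18, Pfkfb3 -1.01 ± 0.19). These 4 list tests passed with the preset correlation and not with an estimated one (adjusted p = 0.306, 0.125, 0.325 and 0.342).

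Disease-associated microglia genes split as well, 12 higher and 8 lower of 31 (13 and 8 adjusted over the list alone, Lpl 3.41 ± 0.31, Ch25h -2.21 ± 0.27), as did complement and phagocytosis genes, 9 higher and 6 lower of 25 (9 and 8 adjusted over the list alone, Marco 2.56 ± 0.33, Fcgr1 -1.65 ± 0.22, C3ar1 -1.65 ± 0.13). Of 35 lysosome genes 15 were higher and 6 lower (17 and 7 adjusted over the list alone), with the glycosidases Gusb (1.19 ± 0.11) and Hexa (1.07 ± 0.11) and their regulator Tfeb (0.90 ± 0.13) among the higher ones (adjusted p = 0.375 with an estimated correlation). Of 27 genes around RIPK1, a kinase that Tbk1 phosphorylates, 12 were lower, including Mlkl (-1.83 ± 0.20) and Casp4 (-1.44 ± 0.20), and 3 higher, including Pycard (1.27 ± 0.25), with adjusted p = 0.114 for the list. Markers of border macrophages and monocytes did not move together: Ly6c2 (3.23 ± 0.26), Pf4 (2.93 ± 0.33), Clec4n (2.79 ± 0.38) and Mrc1 (1.79 ± 0.29) were higher and 2 others of the 10 lower. Their list was not called (adjusted p = 0.151), with a median of 0.129 with median-of-ratios scaling and 0.0535 with quantile normalization. Among 48 markers of astrocytes, the oligodendrocyte lineage, neurons and vascular or stromal cells, 2 were higher and 5 lower.

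In all, 2283 genes were higher and 2100 lower in KO than in WT under LPS. KO against HET, where both carry Cre, gave 1985 and 1827, led by the same names: Hp (3.69 ± 0.33), Gda (3.54 ± 0.28), Susd2 (3.27 ± 0.23), Slfn4 (-5.20 ± 0.32), Ifit1bl1 (-5.19 ± 0.43) and H2-Q6 (-5.11 ± 0.26), and 39 of 40 interferon-stimulated genes were lower (adjusted p = 0.0326 with an estimated correlation). With that p also passed MHC class I genes (19 of 20 lower), the 2 interferon target chemokines, and NF-kB target and cytokine genes (18 of 32 lower, 4 higher), a list that had not passed against WT. With only the groups compared the total was 2536 genes. Tbk1 was lower by -1.73 ± 0.14 and Cx3cr1 higher by 0.94 ± 0.21 in that comparison. Of 1132 genes that LPS raised at least 2-fold in WT, 674 were lower in KO under LPS and 109 higher, and of 4380 that LPS lowered, 971 were higher and 82 lower, against 13.2% lower and 14.4% higher among all genes tested. These classes use the same WT LPS libraries as the comparison, which favours lower values in KO among raised genes. With classes taken from HET instead, which share no library with it, 624 of 1088 raised genes were lower and 125 higher, and 864 of 3926 lowered genes were higher and 118 lower (chosen after the data were seen). Same-numbered HET and WT libraries deviated together under LPS (mean correlation 0.229 across genes), so a part of that bias may remain.

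**Figure D2:**
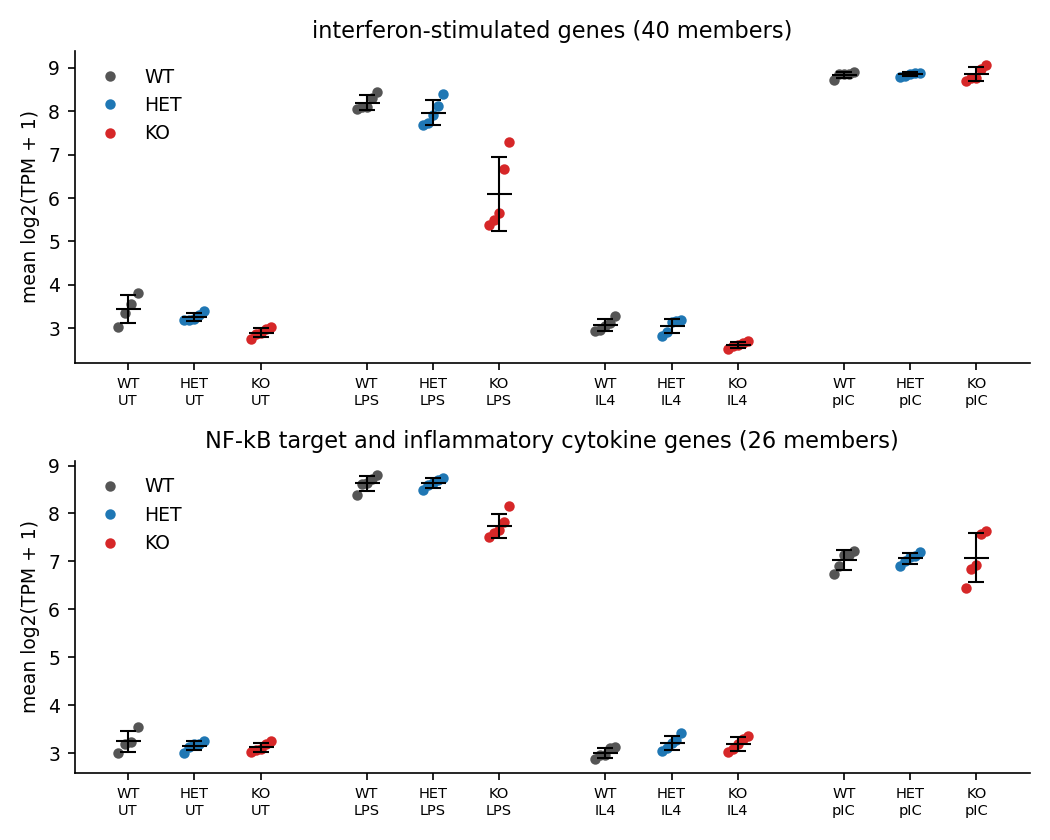
Mean log2(TPM + 1) over 40 interferon-stimulated genes (upper panel) and over 26 NF-kB target and inflammatory cytokine genes (lower panel) in each library, by genotype and treatment. Points are libraries and bars are mean ± SD. With LPS the interferon-stimulated mean is 8.20 ± 0.18 in WT and 6.10 ± 0.85 in KO, while with pIC it is 8.84 ± 0.06 and 8.85 ± 0.16. The pIC libraries come from a separate table.

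The difference between the LPS responses of KO and WT was tested directly. It was called for 1489 genes above and 1118 below 0, so KO and WT responded to LPS differently beyond what they differed by untreated. Hp (4.36 ± 0.48), Susd2 (3.83 ± 0.33) and Acp5 (3.49 ± 0.42) rose more in KO, and Ifit1bl1 (-6.13 ± 0.63), Slfn4 (-5.84 ± 0.47) and H2-Q6 (-5.63 ± 0.38) rose less. The response of Tbk1 differed by -1.07 ± 0.21 (adjusted p = 0.000177) and that of Cx3cr1 by 1.05 ± 0.30 (adjusted p = 0.0115, and not called at 0.0571 with only the groups compared). MHC class I genes (18 of 20 lower) and immediate early genes (9 lower, 1 higher of 16) passed with an estimated correlation (adjusted p = 0.0292 for either), whereas interferon-stimulated genes, 30 of 40 lower (31 adjusted over the list alone), did not (adjusted p = 0.0705). Cholesterol synthesis genes had 17 of 22 called above 0 (21 adjusted over the list alone) and oxidative phosphorylation genes 21 of 33 (26 adjusted over the list alone), neither passing with an estimated correlation (adjusted p = 0.253 and 0.192). The median gene shifted by 0.119, and with median-of-ratios scaling the calls were 1142 above and 1654 below 0.

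Few genes separated HET from WT under LPS. Only Rpsa, a ribosomal protein and laminin receptor, and its pseudogene Rpsa-ps10 were called between HET and WT under LPS (0.68 ± 0.08, adjusted p = 1.2e-05, and 0.60 ± 0.10, adjusted p = 0.0071). Both were higher, and a pseudogene this similar can take reads of the gene itself. With only the groups compared Rpsa was not called (adjusted p = 0.297). At an unadjusted p under 0.05 there were 889 genes against 795 expected with no effect. Leaving out HET LPS 5 raised the count to 64 genes, leaving out HET LPS 3 to 4, and leaving out WT LPS 5 lowered it to 1. The difference between the LPS responses of HET and WT was called for 0 genes by limma (604 at an unadjusted p under 0.05), with Tbk1 at -0.14 ± 0.21 and Cx3cr1 at -0.01 ± 0.30. Of 32 lists 7 passed with the preset correlation for HET against WT under LPS and 10 for the difference between the responses, among them glycolysis (medians -0.217 and -0.323), and none with an estimated correlation (glycolysis adjusted p = 0.385 and 0.19).

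Untreated cultures of the 3 genotypes differed in few genes. In KO against WT limma called 5: Tbk1 (-1.24 ± 0.15), the interferon-stimulated Oasl2 (7.68 ± 2.50 against 19.7 ± 5.23 TPM, -1.27 ± 0.24, adjusted p = 0.018) and the unnamed model Gm23935 (-3.03 ± 0.61) were lower, and Rpsa (1840 ± 138 against 1144 ± 77.9 TPM, 0.68 ± 0.09) and Rpsa-ps10 (0.59 ± 0.11) higher, of which the unnamed model and the pseudogene were named after their values were seen. Oasl2 was not alone in its direction. Of 40 interferon-stimulated genes 39 were below 0 in KO (median -0.437), 16 of them called lower when adjusted over the list alone, and the list passed camera with the preset correlation (adjusted p = 3.58e-15) and not with an estimated one (adjusted p = 0.347). The call of Oasl2 was lost without KO UT 2 (adjusted p = 0.126), WT UT 1 (0.0869), WT UT 2 (0.0619) or WT UT 3 (0.338) with only the groups compared (0.526) and with median-of-ratios scaling (0.0974), under which 2 genes were higher and 1 lower in all, while quantile normalization gave 2 and 2. The total also fell to 2 genes without KO UT 2 or WT UT 3 and to 3 without WT UT 2.

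HET against WT untreated called 2 genes, Rpsa (1884 ± 133 against 1144 ± 77.9 TPM, 0.72 ± 0.09, adjusted p = 1.25e-05) and Rpsa-ps10 (0.69 ± 0.11, adjusted p = 0.00122). None of 35 lysosome genes was called alone, but 1 list, that of the lysosome, passed with an estimated correlation (median 0.178, adjusted p = 0.0395), where the cathepsins Ctsd and Ctsb stood at 0.30 ± 0.19 and 0.17 ± 0.12. KO against HET untreated called only Tbk1 (-0.80 ± 0.14, adjusted p = 0.0213), with Cx3cr1 at -0.13 ± 0.21. That call was lost in 8 of the fits that left out 1 library, of KO UT 1, 3, 4 or 5 or of HET UT 1, 2, 3 or 4, with adjusted p from 0.0516 to 0.202, with only the groups compared (0.538) and with median-of-ratios scaling (0.0867). At an unadjusted p under 0.05 there were 877, 410 and 290 genes in the 3 comparisons.

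Rpsa was higher in the genotypes with Cre in each treatment, although HET against WT under pIC did not pass adjustment over all genes (0.68 ± 0.11, adjusted p = 0.215). Its level was 524.5 ± 75.6 TPM in WT, 838 ± 94.3 in HET and 1185 ± 90.9 in KO with LPS, at 1369 ± 113, 2158 ± 162 and 2192 ± 135 with IL4, and at 674 ± 25.2, 1085 ± 54.3 and 1104 ± 225 with pIC. Rpsa (Entrez 16785, plus strand of chromosome 9 from 120127689 to 120132369) lies beside Slc25a38 (Entrez 208638, 120110374 to 120124504), a mitochondrial glycine carrier, and both lie beside Cx3cr1 (Entrez 13051, minus strand, 119901616 to 120069879). Over untreated, LPS and IL4 libraries together, Slc25a38 was higher in HET than in WT by 0.52 ± 0.08 and in KO by 0.40 ± 0.08, and Rpsa by 0.69 ± 0.05 and 0.85 ± 0.05. Of the other genes of that stretch, Gm33858, which overlaps the start of Cx3cr1 on the other strand, stood at 0.27 ± 0.12 in HET and 0.16 ± 0.12 in KO, Gm2449 at 0.21 ± 0.15 and -0.06 ± 0.15, and Cx3cr1 at 0.14 ± 0.12 and 0.36 ± 0.12. Wdr48 stood at -0.03 ± 0.05 and -0.12 ± 0.05, Gorasp1 at 0.02 ± 0.09 and 0.08 ± 0.09, and Csrnp1 at -0.08 ± 0.12 and -0.38 ± 0.12. Mobp stood at -0.47 ± 0.33 and -0.44 ± 0.33, and Myrip at -0.16 ± 0.18 and -0.31 ± 0.18. These errors count libraries of the same culture as independent. With 1 value per culture (14 cultures with all 3 treatments, a calculation added after the data were seen) Slc25a38 stood at 0.50 ± 0.11 in HET and 0.38 ± 0.11 in KO, Rpsa at 0.66 ± 0.05 and 0.83 ± 0.05, and Csrnp1 at -0.11 ± 0.10 and -0.40 ± 0.10. Gm33858 and Cx3cr1 stood at 0.25 ± 0.17 and 0.06 ± 0.15 in HET. The genes of this stretch were chosen after Rpsa had been seen.

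**Figure D3:**
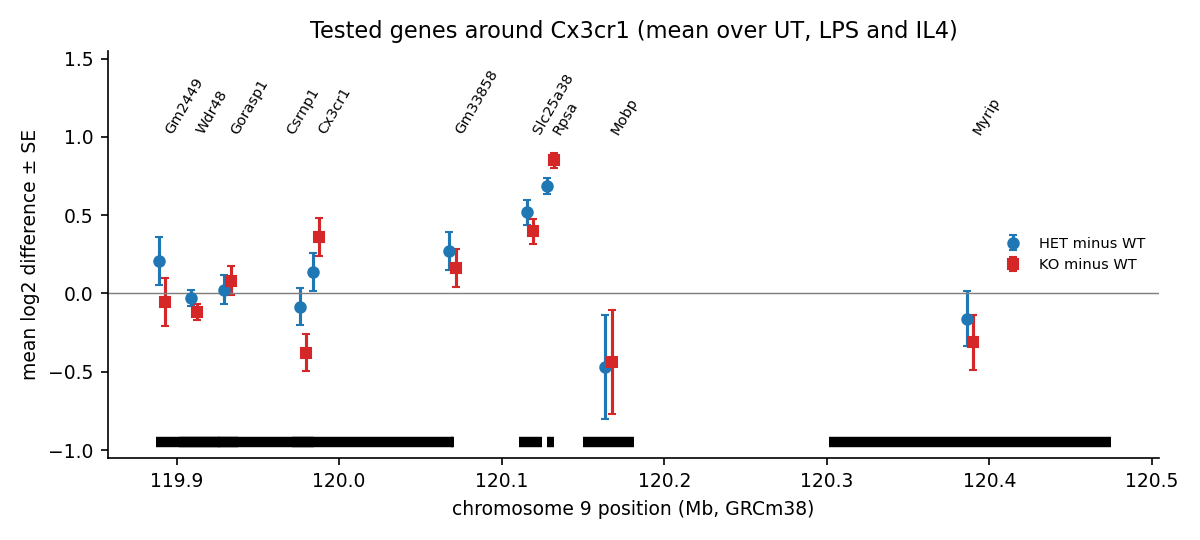
Mean log2 difference from WT (vertical axis, ± SE) over the untreated, LPS and IL4 libraries for each tested gene within 300 kb of Cx3cr1 on chromosome 9 (horizontal axis, Mb, GRCm38). Circles are HET minus WT, squares KO minus WT, and black bars mark the extent of the genes. Slc25a38 and Rpsa, side by side, stand at 0.52 and 0.69 in HET.

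IL4, which drives macrophages to an alternative, repair-associated state, raised its known targets in every genotype. In WT Arg1, arginase, went from 0.202 ± 0.237 to 1320 ± 288 TPM (10.09 ± 0.37), and Retnla from 0.0690 ± 0.138 to 463 ± 332 (8.55 ± 0.26). Tmem26 went from 0.184 ± 0.0949 to 53.0 ± 14.4, Cd74, the MHC class II chaperone, from 11.4 ± 3.59 to 387 ± 104, Postn, periostin, from 0.562 ± 0.121 to 45.8 ± 9.91 and Itgax from 7.88 ± 3.13 to 135 ± 50.3. Tlr2 (-1.98 ± 0.17), Cd14 (-1.67 ± 0.24) and the lectin Clec4n (-1.97 ± 0.40) fell, as did Icosl (-1.85 ± 0.20), Adgb (-1.84 ± 0.22) and Dkk2 (-1.66 ± 0.18). Of 32 IL-4 response genes 24 rose and 1 fell (25 and 3 adjusted over the list alone), with Egr2 at 3.79 ± 0.36 and Mgl2 at 3.50 ± 0.23, and of 13 MHC class II genes 8 rose and 1 fell (9 and 3 adjusted over the list alone), with H2-Aa at 2.82 ± 0.37 and H2-Eb1 at 2.15 ± 0.30. Both lists passed with an estimated correlation (adjusted p = 7.46e-10 and 0.00158).

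The phagocytic receptors Cd36 (2.06 ± 0.30) and Fcgr2b (1.18 ± 0.16) were among 6 complement and phagocytosis genes that rose, while 2 fell (6 and 4 adjusted over the list alone), and the proton pump subunit Atp6v0d2 (3.43 ± 0.33) led 8 lysosome genes that rose, while 2 fell (9 and 2 adjusted over the list alone). Neither list passed with an estimated correlation (adjusted p = 0.365 and 0.289). Cx3cr1 (-1.30 ± 0.22), P2ry13 (-1.21 ± 0.20) and Gpr34 (-0.76 ± 0.18) were among 5 of 20 homeostatic genes that fell (6, with 1 that rose, adjusted over the list alone), with no list call (adjusted p = 0.0668). In all 585 genes rose and 419 fell in WT, 631 and 491 in HET, and 856 and 482 in KO. With the replicate number, shared by all genotypes, as a block the counts were 1416 genes in WT, 1932 in HET and 2024 in KO. Libraries with the same number were taken as 1 culture within a genotype, and with that culture as a block the counts, given in the last part, were higher still. The median gene shifted by -0.11 in WT, and with median-of-ratios scaling 702 rose and 225 fell there, and 685 and 348 in HET.

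Arg1 rose by 10.12 ± 0.35 in HET and 10.06 ± 0.35 in KO, Retnla by 8.80 ± 0.24 and 8.95 ± 0.24 and Tmem26 by 5.34 ± 0.17 and 5.50 ± 0.17. Tlr2 (-1.89 ± 0.16 and -1.90 ± 0.16) and Dkk2 (-1.77 ± 0.17 and -1.88 ± 0.17) fell in both. Cd14 in HET (-1.62 ± 0.23) and Icosl in KO (-1.75 ± 0.19) completed the named genes. The differences between the IL4 responses of KO or HET and that of WT were called for 0 genes by limma, with 262 and 254 genes at an unadjusted p under 0.05 against 795 expected with no effect. Those tests treat libraries of the same culture as independent.

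Under IL4, KO and WT differed in 7 genes. Tbk1 (-1.49 ± 0.14) and the interferon-stimulated Rtp4 (1.67 ± 0.650 against 6.76 ± 3.66 TPM, -1.45 ± 0.29, adjusted p = 0.0316) and Slfn5 (4.63 ± 0.723 against 11.1 ± 2.59 TPM, -1.08 ± 0.20, adjusted p = 0.0165) were lower, and Rpsa (0.68 ± 0.08) and its pseudogenes Rpsa-ps10, Rpsa-ps2 and Rpsa-ps7 (0.65 ± 0.10, 0.82 ± 0.16 and 1.00 ± 0.19), named after their values were seen, higher. Of 40 interferon-stimulated genes 37 were below 0 (median -0.363) and 14 lower when adjusted over the list alone, with adjusted p = 1.06e-20 from camera and 0.134 with an estimated correlation. MHC class II genes lay above 0 in 12 of 13 (median 0.266), a list call that held with an estimated correlation (adjusted p = 0.0362) although no member passed alone. Slfn5 was not called without KO IL4 3 (adjusted p = 0.068), KO IL4 5 (0.0924), WT IL4 1 (0.0761) or WT IL4 3 (0.101), nor Rtp4 without any of these (0.068, 0.191, 0.26 and 0.168) or without KO IL4 2 (0.132), KO IL4 4 (0.0567) or WT IL4 4 (0.0833). Neither Slfn5 nor Rtp4 was called with only the groups compared (0.106 and 0.75) or with median-of-ratios scaling (0.0757 and 0.0575), and Rtp4 was not called with quantile normalization (0.0505), without a filter (0.058) or with the Xist level as a covariate (0.0807). The total was 3 genes without KO IL4 3, KO IL4 5 or WT IL4 1 and 4 without WT IL4 4, and the split was 5 higher and 1 lower with median-of-ratios scaling and 5 and 2 with quantile normalization.

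HET against WT under IL4 called Rpsa (0.66 ± 0.08, adjusted p = 2.74e-05) and Rpsa-ps10 (0.54 ± 0.10, adjusted p = 0.0392), Rpsa not with only the groups compared (adjusted p = 0.0635), and the count fell to 1 gene without HET IL4 1, 2 or 4 or WT IL4 1, 3, 4 or 5. KO against HET under IL4 called Tbk1 (-0.99 ± 0.14, adjusted p = 3e-04, but 0.513 with only the groups compared), and 2 or 3 genes without KO IL4 2 or HET IL4 2 (2 each) or HET IL4 3 (3). At an unadjusted p under 0.05 there were 430 genes in KO against WT, 357 in HET against WT and 387 in KO against HET.

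The pIC libraries asked whether Tbk1 matters when the stimulus is double-stranded RNA. Here interferon-stimulated genes did not separate the genotypes as a group. Their mean stood at 8.84 ± 0.06 (SD) in WT, 8.85 ± 0.05 in HET and 8.85 ± 0.16 in KO on the log2(TPM + 1) scale. Of 40 genes 7 were higher and 2 lower in KO than in WT (15 and 5 adjusted over the list alone), with Oasl1 lower (-1.34 ± 0.21) and Ifit2 (0.49 ± 0.11) and Slfn5 (0.41 ± 0.07) higher, and the list test was lost with an estimated correlation (adjusted p = 0.456). With median-of-ratios scaling 12 were higher and 1 lower, and with quantile normalization 5 and 3. Cxcl10, chosen after its values were seen, was at 2786 ± 172 TPM in WT and 3216 ± 212 in KO. Among interferons and their early target chemokines, Ccl5 was lower (13130 ± 6510 against 28760 ± 4490 TPM, -1.29 ± 0.30) and the interferons Ifna5 (1.77 ± 0.34) and Ifna2 (1.33 ± 0.18) higher, from levels below 1 TPM in WT and within a family of near-identical genes (list adjusted p = 0.034 with an estimated correlation).

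Genes of uptake and of the disease-associated state were higher in KO under pIC. Of 25 complement and phagocytosis genes 14 were higher and none lower (16 and 1 adjusted over the list alone, median 0.472, adjusted p = 0.000249 with an estimated correlation): Marco was at 20.7 ± 10.9 against 4.45 TPM (1.88 ± 0.29), the Fc receptor Fcgr3 at 62.0 ± 30.4 against 22.8 ± 9.36 (1.39 ± 0.32) and the integrin Itgam at 107 ± 29.9 against 46.8 ± 14.6 (1.20 ± 0.22). Of 30 disease-associated microglia genes 9 were higher and none lower (12 adjusted over the list alone, adjusted p = 0.034 with an estimated correlation), with lipoprotein lipase (Lpl) at 341 ± 92.4 against 94.8 ± 7.65 TPM (1.80 ± 0.16), Itgax at 1.23 ± 0.16, Trem2 at 1.22 ± 0.30 and lysozyme (Lyz2) at 1.02 ± 0.21. Hp (2.86 ± 0.50), Ms4a4a (2.48 ± 0.32) and Fn1 (2.05 ± 0.37) were also higher. Of 15 immediate early genes 3 were higher (Egr2 1.21 ± 0.16, Zfp36 0.84 ± 0.14, Junb 0.39 ± 0.08, 4 adjusted over the list alone, list adjusted p = 0.0373), where Zfp36 had been lower under LPS. The list of IL-4 response genes also passed (adjusted p = 0.034 with an estimated correlation), with 5 of 21 higher, among them Fn1 and Egr2, and 4 lower, among them Ccl22 (-1.91 ± 0.41) and Klf4 (-1.37 ± 0.35).

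Genes lower in KO under pIC included the keratin Krt16 (2.33 ± 2.12 against 20.8 ± 7.54 TPM, -2.93 ± 0.41), cyclin E1 (Ccne1, -2.36 ± 0.34), the prostaglandin receptor Ptger2 (-2.32 ± 0.18), Intu (-2.29 ± 0.28), the activin subunit Inhbb (-2.16 ± 0.20) and the tryptophan-degrading Kynu (-2.11 ± 0.23). Autophagy genes, where Tbk1 acts on cargo receptors, had 10 of 31 lower and none higher (16 adjusted over the list alone, Calcoco1 -0.46 ± 0.10, Ulk1 -0.46 ± 0.11, Atg13 -0.42 ± 0.07), with adjusted p = 0.136 for the list with an estimated correlation and 5 lower with median-of-ratios scaling. Of 20 MHC class I genes 4 were lower and 1 higher (7 and 1 adjusted over the list alone, H2-Q7 -1.40 ± 0.31, H2-Q6 -1.25 ± 0.28), and of 12 MHC class II genes 4 were lower (5 adjusted over the list alone, H2-Aa -1.35 ± 0.38, H2-Eb1 -1.13 ± 0.31), neither list being called (adjusted p = 0.134 and 0.25). With median-of-ratios scaling 2 MHC class I genes were lower and 1 higher, and 1 MHC class II gene was lower. With quantile normalization these were 4, 1 and 1. H2-Aa and H2-Eb1 missed the threshold with median-of-ratios scaling (adjusted p = 0.0504 and 0.0508) and with quantile normalization (0.0618 and 0.0643).

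**Figure D4:**
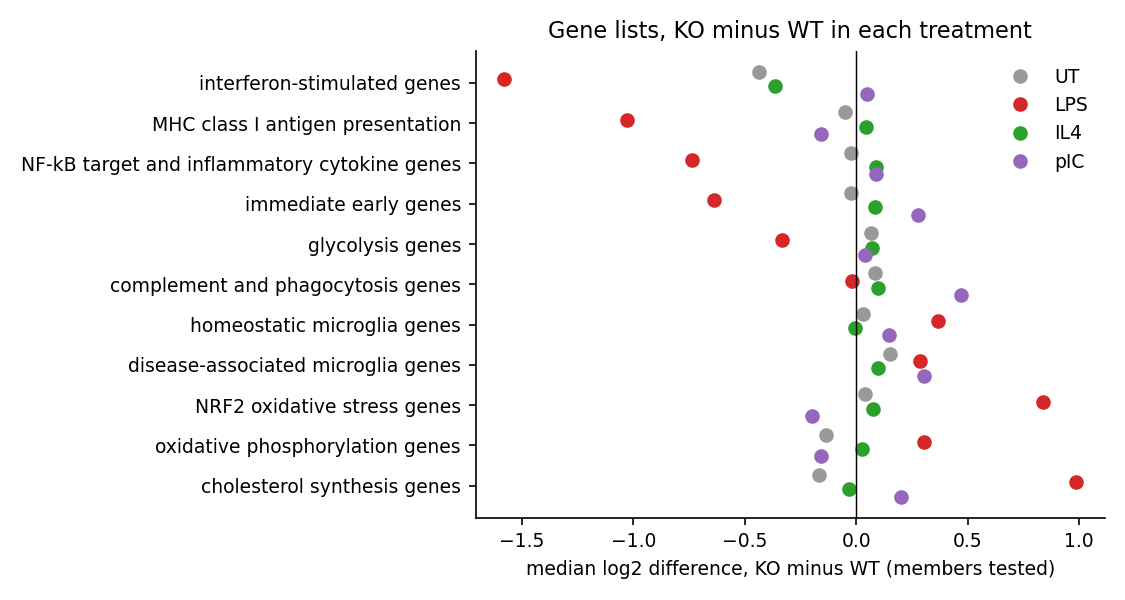
Median log2 difference of KO minus WT (horizontal axis) over the tested members of 11 gene lists, 1 point per treatment. Interferon-stimulated genes stand at -1.58 with LPS, -0.437 untreated, -0.363 with IL4 and 0.0474 with pIC, and complement and phagocytosis genes at 0.472 with pIC. Treatments were tested separately, pIC in its own table.

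In all 473 genes were higher and 1129 lower in KO than in WT under pIC. The median gene shifted by -0.112, and the balance turned with the scaling, to 724 higher and 470 lower with median-of-ratios scaling and 654 and 562 with quantile normalization. Without WT pIC 1 the total was 1046 genes, and with only the groups compared 1005. KO against HET gave 229 higher and 501 lower genes (289 and 216 with median-of-ratios scaling, 274 and 274 with quantile normalization), with Ms4a4a (1.93 ± 0.32), Mmp13 (1.82 ± 0.37) and cyclin D1 (Ccnd1, 156 ± 50.3 against 52.1 ± 4.78 TPM) highest and Krt16 (-2.59 ± 0.41), Ccne1 (-2.08 ± 0.34) and Inhbb (-1.97 ± 0.20) lowest, Tbk1 at -1.16 ± 0.11 and Cx3cr1 at 0.63 ± 0.51 (not called). That total was 440, 402 or 464 genes without HET pIC 1, 2 or 4. It was 299 with the Xist level of each library as a covariate (added after the data were seen), 356 with only the groups compared and 1211 with the replicate block. In that comparison 5 of 25 complement and phagocytosis genes were higher (13 and 1 lower adjusted over the list alone, adjusted p = 0.00115 with an estimated correlation). HET against WT called 0 genes under pIC in limma, with 311 at an unadjusted p under 0.05 against 696 expected and 1 gene without HET pIC 5, while the complement and phagocytosis list lay above 0 (median 0.137, adjusted p = 0.027 with an estimated correlation).

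The KO against WT differences under LPS and pIC come from separate libraries. By their sex-chromosome transcripts these appear to be of the same cultures, so differences between cultures, such as sex, enter both. No number of shared genes expected without an effect is therefore given. Over the 13752 genes tested in both, 127 were higher in both and 213 lower in both. Hp, Fn1, Marco and Lpl were higher under either stimulus, and Trib3, H2-Q7, Oasl1, Ccl5 and Ptger2 lower. Opposite calls were as common: 165 genes were lower under LPS and higher under pIC, among them Mmp13 (-3.91 and 1.40), Fcgr4 (-2.70 and 0.96) and C3ar1 (-1.65 and 0.94), and 209 higher under LPS and lower under pIC, among them Ccl22 (2.13 and -1.91). Mmp13, Fcgr4, Ccl22, Trib3 and Ptger2 were chosen for this comparison after their values were seen. With LPS the KO mean of Ccl22 was 56.7 TPM, and 23.2 without KO LPS 5, and the WT mean 6.28, and 4.04 without WT LPS 5. Across genes, which are not independent replicates, the log2 differences had a Pearson r of 0.0673 and a Spearman rho of -0.00639. With median-of-ratios scaling the counts were 140, 119, 265 and 81 in the same order.

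Transcripts of the sex chromosomes showed that the cultures differed in the sex of the pups. Per genotype, 3 of 5 KO cultures had Xist without Ddx3y and 2 had both. In HET 1 culture had Xist alone, 2 Ddx3y alone and 2 both, and in WT 1 had Ddx3y alone and 4 both. KO against WT under LPS gave 4211 genes with the Xist level of each library as a covariate, a fit added after the data were seen. The same covariate lowered KO against HET under pIC from 730 to 299 genes and KO against WT under IL4 from 7 to 4.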

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

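Of the tests in this part, that on Slc25a38, that with the Xist level, that of a ceiling and the regroupings of libraries were stated before their values were seen, and the others were chosen after the result was seen.

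Rpsa, near Cx3cr1, was higher in HET and KO than in WT, and where Cre lies in the genome was not tested. Slc25a38, the neighbouring gene, was higher in HET by 0.52 ± 0.08 (SE) on the log2 scale, which fits extra copies of that region, although Cx3cr1 itself differed by only 0.14 ± 0.12. The summed TPM of Rpsa and its pseudogenes was higher by 0.68 ± 0.05, which argues against reads moved among them as the cause. Only pseudogenes that carry the Rpsa name were summed, so reads from other copies stay open. Rpsa differed between KO and HET by 0.16 ± 0.05 on average, by -0.03 ± 0.08 untreated and 0.02 ± 0.08 with IL4. That argues against a cause graded by Tbk1 copies untreated and with IL4. HET also lacked 1 Tbk1 copy and no group had Cre with Tbk1 intact. An effect already complete in HET can therefore not be told from one of Cre. With LPS Rpsa differed by 0.50 ± 0.08, so a part of loss of Tbk1 in the LPS value stays open. These errors count libraries of the same culture as independent. With 1 value per culture Slc25a38 differed by 0.50 ± 0.11, the sum by 0.66 ± 0.05 and Rpsa between KO and HET by 0.16 ± 0.05, which leaves these readings as they are. A strain variant linked to Cre stays open, since no test here separates it from extra copies.

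KO and WT differed in 4383 genes under LPS, and the response itself differed in 2607 genes by a test of the difference, which is why it is listed here. If a weaker stimulus in KO scaled every response down alike, no more LPS-raised genes would respond more strongly there than expected with no difference. Of 1088 genes raised in HET, 79 did and 4.44 were expected (91 and 8.14 with median-of-ratios scaling, 91 and 6.66 with quantile normalization), among them Marco (by 2.96) and Mmp9 (by 3.09). Of 100 regroupings of the cultures 1, the real one, gave as many in the direction of the group with more KO cultures (highest other 37), and 4 in either direction (highest other 129). In the direction of KO these counts argue against a weaker stimulus that scales every response down alike as the whole cause. In either direction chance is left open, since other regroupings gave as many and not all 126 were drawn. A weaker stimulus is therefore not excluded, as responses need not scale alike, and as a part it stays open, since 506 of these genes responded less in KO. The first limit, on the percent of genes raised in WT that were higher in KO, had left this open at 9.63%, and it was replaced after the values were seen because it compared levels, not responses, and used the WT LPS libraries on both sides. With the Xist level fitted 4211 genes were left, which argues against the sex of the pups as the whole cause, as far as Xist measures it. That level mostly parts cultures with Ddx3y alone from the others, and Ddx3y was not fitted, so sex as a part stays open. Of 48 markers of astrocytes, oligodendrocyte lineage, neurons and stromal cells, 10.42% were called in the commoner direction, under a limit set after the result was seen. The markers varied widely between libraries, with an SD of the oligodendrocyte lineage mean under LPS of 0.86 in WT and 0.694 in KO (log2 scale). Few calls can therefore not exclude another share of these cells. Of 10 border macrophage and monocyte markers 4 were higher and 2 lower in KO, and of 2 neutrophil and mast cell markers 1 was higher, so another mix of these cells stays open.

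Interferon-stimulated genes were lower in KO under LPS and not under pIC. The ratio of KO to WT Tbk1 transcript was 0.289 under pIC, 0.198 under LPS and 0.419 untreated. It was thus higher under pIC than under LPS, as more Tbk1 left under pIC would give, but lower than in untreated cells. A value per gene does not show whether the deleted exon was absent. More Tbk1 left under pIC can therefore be neither shown nor excluded. The first limit of that test compared pIC with untreated cells alone, which was wrong because the pattern compares pIC with LPS, and it was restated after the values were seen. In WT the mean of these genes was higher under pIC than under LPS by 0.64, as a ceiling on the transcripts would give. The SD between libraries was 0.064 under pIC and 0.175 under LPS, which missed the other limit stated for a ceiling. A ceiling is thus neither shown nor excluded. A route to interferon that needs Tbk1 less under pIC could not be tested with these libraries.

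Single libraries far from the rest of their group were found in 18 of 217 groups of values, where chance gives about 1 in 20, and a lower limit of 5 TPM on the group mean was added after the first results were seen. In the first table these were Tbk1 in WT UT 2 (53.8 TPM against 45.1 to 46.0 in the others), Retnla in WT IL4 2 (1046 against 252 to 398), Slfn5 in HET UT 2 (21.3 against 13.6 to 15.0), Slc25a38 in HET LPS 3 (19.9 against 24.4 to 25.6), and Hp and Marco in HET LPS 4 (23.5 against 6.55 to 9.91 and 1135 against 708 to 823). KO UT 5 had fewer genes with at least 1 TPM (13590 against 14120 to 14290) and a larger share of TPM in its 50 most abundant genes (33.3% against 28.8% to 29.4%). Cxcl10 and Rsad2 stood high in KO LPS 1 (292 against 9.58 to 82.0 and 115 against 8.90 to 35.7), and Cx3cr1 and Fn1 low in KO IL4 5 and KO IL4 3 (229 against 298 to 322 and 479.5 against 957.5 to 991). With pIC they were Rpsa in WT 3 (630 against 677 to 691), Hp in WT 4 (17.1 against 5.40 to 7.92) and in KO 4 (181 against 35.7 to 63.6), the share of the 50 most abundant genes in WT 1 (28.5% against 29.7% to 30.1%), Rtp4 in HET 5 (517 against 418.5 to 440.3) and Slfn5 in HET 1 (361 against 398 to 406).

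Libraries were also regrouped at random, with the real grouping counted among 100 drawn of 126 possible, or among 85 where every pair of same-numbered libraries deviated together. For KO against WT only the real grouping was as large under LPS (4383 genes, highest other 2332) and pIC (1602 genes, highest other 172). The same held for KO against HET under LPS (3812, highest other 2212) and pIC (730, highest other 4), and for the difference in LPS responses (2607, highest other 512). These counts argue against chance if the libraries of the genotypes are independent. Chance is not excluded, since 26 groupings were not drawn. If replicate numbers pair the genotypes, too few groupings part every pair for a share under 0.05. For KO against WT 2 of the 100 drawn were as large untreated (5 genes, highest other 5) and 4 under IL4 (7 genes, highest other 88). As 26 of the 126 were not drawn and others reached the real count, chance is left open for both. The grouping with 88 genes kept KO and WT libraries of the same number on the same side, except for number 1. It thus points to a structure that follows the replicate number and not the genotype. For LPS against UT the real grouping was the largest, 1 of those drawn, in WT, HET and KO (12064 against a highest other of 11455, 11772 against 9744, and 11078 against 8916), as it was for IL4 (1004 against 694, 1122 against 827, and 1338 against 476). Replicate numbers pair these libraries, so only 16 groupings part every pair, too few for a share under 0.05, and the highest others were 9425, 7818 and 7273 for LPS and 319, 18 and 61 for IL4. The same holds for HET against WT untreated, with 2 genes and a highest other of 4. Chance cannot be excluded for HET against WT untreated (6 as large, 2 genes, highest other 4), under LPS (32, 2 genes, highest other 791) or IL4 (8, 2 genes, highest other 728), nor for KO against HET untreated (8, 1 gene, highest other 22) and under IL4 (7, 1 gene, highest other 2). Where 0 genes were called, all 100 groupings are as large by construction, so nothing follows about chance. That holds for HET against WT under pIC (highest other 2) and for the differences in response of KO to IL4 (1), HET to LPS (57) and HET to IL4 (1). Groupings with many times the real count, 14 of them above 5 times for HET against WT under LPS, point to a structure that is not the genotype. The largest of these under LPS and IL4 kept HET and WT libraries of the same number on the same side, except 1 number. Same-numbered HET and WT libraries deviated together, with mean correlations of 0.229 under LPS and 0.267 under IL4 (other pairs -0.0566 and -0.0656). That structure thus follows the replicate number, and what the number stands for across genotypes is not known.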

How the results depend on the processing

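Depth per library is unknown, since TPM keeps none, so its effect on genes with low values was not tested. Of 22 counts, 21 stayed within 1.5 times the reported one with a pseudocount of 0.1, 16 without a filter, 20 with median-of-ratios scaling, 22 with quantile normalization, 13 with only the groups compared (fewer libraries to estimate the spread), 17 with the replicate block and 20 with the Xist level. Of 142 named values, 136 to 142 kept direction and side of the threshold in those settings (134 with only the groups compared). For the other changes the cause was not tested. No filter: KO against WT untreated 10 genes, HET against WT untreated 11, under LPS 9 and IL4 1, KO against HET untreated 2, HET by LPS difference 1. Median-of-ratios scaling: KO against WT untreated 3, KO against HET untreated 0. Pseudocount 0.1: KO against HET, IL4, 4. Only the groups compared: KO against HET untreated 0, LPS 2536, IL4 0 and pIC 356, KO against WT IL4 2 and pIC 1005, HET against WT LPS 1, IL4 0 and pIC 1. Replicate block: HET against WT LPS 4, KO against WT IL4 11, KO against HET pIC 1211, IL4 against UT 1932 in HET and 2024 in KO. Genotype by replicate block: IL4 against UT 1655 in WT, 2467 in HET and 2535 in KO. Chosen after seeing the data: Xist level, KO against WT IL4 4 and KO against HET pIC 299, and without replicate 5 of every group, KO against HET untreated 0 and pIC 414, and HET against WT LPS 8. With an estimated correlation 62 of 299 list calls stayed. Leaving out 1 library gave 2 to 5 genes for KO against WT untreated, 0 to 1 for KO against HET untreated, 1 to 64 for HET against WT under LPS, 3 to 7 for KO against WT, 1 to 3 for HET against WT and 1 to 3 for KO against HET under IL4, 1046 to 1776 for KO against WT, 402 to 710 for KO against HET and 0 to 1 for HET against WT under pIC. Reversed were Tbk1, LPS against UT in KO, 0.35 with median-of-ratios scaling and 0.27 with quantile normalization. So were Tbk1, IL4 against UT in WT, 0.0006738 with median-of-ratios scaling, and Cx3cr1, HET by LPS difference, 0.0235 with quantile normalization. Without 1 library Cx3cr1 ranged from -0.156 to 0.2004 in the HET by LPS difference, above 0 in 9 fits, and from -0.0479 to 0.148 in HET against WT under IL4, below 0 without HET IL4 1, HET IL4 2 or WT IL4 5.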
